A study of Caenorhabditis elegans with 21 samples.

How the data were processed

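Total RNA was sequenced from early embryos of C. elegans of 7 genotypes, with 3 libraries per genotype and 21 libraries in all. Per the labels, RNA was isolated with a DNase step, ribosomal RNA was depleted from 5 µg of total RNA, libraries were made with an Illumina TruSeq kit, and reads were processed with genome build ce10. The authors deposited raw read counts per fixed window of 500 bp, without strand, gene names or repeat names. The windows cover chromosomes I to V and X without gaps, 200547 in all, and the last window of each chromosome ends at the ce10 chromosome length. The aligner, the counting tool, the treatment of reads with several matches and the counting of reads that span 2 windows are not stated in the labels. Columns were matched to genotypes by name. The letters a, b and c of the columns were not tied to the replicate numbers of the titles, so libraries are named by genotype and letter. A further 6 columns of per-sample values, which could not be matched to a sample, were not used here.

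Depth was 22275571 to 67553226 reads per library. The tested windows held 95.85 to 99.67% of each library's reads, and TMM factors ran from 0.737 to 1.27. Precision is limited by the counts behind each window: 0 reads over the 3 libraries of a genotype allow up to 3. Ratios against a group with 1 to 3 reads carry an exact binomial 95% interval (Clopper-Pearson), and a ratio against 0 reads is a lower bound that uses the floor of 3 reads over the group. For single windows these compare the reads pooled over the 3 libraries, and for stretches the mean level over that floor. Both cover counting error only.

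Counts were fitted in R 4.3.3 with edgeR 4.0.16 (TMM, filterByExpr by genotype with its minimum count of 10, glmQLFit and glmQLFTest) with 1 coefficient per genotype over all 21 libraries, which leaves 14 residual degrees of freedom. This kept 97353 windows. The comparisons were each mutant or double mutant against N2, each double mutant against its nrde-3 or lin-61 parent, the double mutants against each other, and the interaction (nrde-3 met-2 minus nrde-3 set-25) minus (lin-61 met-2 minus lin-61 set-25). A window was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison. Called windows of 1 direction were joined into regions across gaps of at most 1 window. The design, the alternatives and the rule for named items were fixed before the data were examined, for genes. Since the counts are per window, the same tests and rule were applied to windows. The rule takes the 7 highest and 7 lowest log2 fold changes in lin-61 and nrde-3 against N2 and in each double mutant against its parent, and the 3 highest and 3 lowest in the other comparisons. It takes them among called windows with an average log2 CPM of at least 1 and with all 3 libraries of 1 group above all 3 of the other. Only 1 window per region was named.

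Tests of gene lists and of repeat families, and values for the 4 mutated genes, were not run, since the counts carry no gene or repeat names and the annotation at hand is for another genome build than ce10. In place of the mutated genes, the labels were checked by a search over 126 splits of the genotypes for windows with at least 5 CPM in every library of the other genotypes and at most 0.25 of that level in the low ones, and by the chromosome that the labels give for each mutation.

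The library prefix in the titles (875 or 1121) is fixed by genotype and cannot be a term beside it. It was therefore a term only in an alternative model with additive terms for the 4 mutations. Other alternatives were RLE scaling, no filter on low counts, only the libraries of the groups compared, DESeq2 1.42.0 (Wald test), and leaving out each library in turn. Fits with fewer libraries reran the filter on low counts, so their tested windows differed from those in the fit of all libraries. Subtraction of background was added after the data were seen: the mean reads per window in 32179 windows with at most 2 reads over the 6 libraries of prefix 875 were taken off each library. The comparison of the libraries labelled lin-61 met-2 with nrde-3 set-25 was added in the same way. For the autosomal arms, the called windows were set against 1000 circular rotations of the calls along the chromosomes, and the p was adjusted over 30 comparisons.

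The pipeline was tested on simulated data with the windows and library sizes of these libraries. Each window had 1 mean level in all genotypes and a spread set by its level alone. For lin-61 against N2, 20 of 100 windows changed by 1 on the log2 scale and 81 of 100 changed by 2 were recovered with their sign, and 7 calls (6.48%) were false. For nrde-3 set-25 against nrde-3 the numbers were 18, 81 and 2 (1.98%). These rates need not hold for the real libraries, where far more windows were called and the spread differed between genotypes. Patterns and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.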

Results

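The data were total RNA sequencing libraries from early embryos of Caenorhabditis elegans, collected before the bean stage at about 1 to 300 cells and grown at 20 °C. They came from 7 genotypes with 3 libraries each, 21 libraries in all. N2 is the wild type. The mutations, named by the labels, are in lin-61 on chromosome I, which encodes a protein with MBT domains, nrde-3 on X, which encodes an Argonaute of nuclear RNA interference, and met-2 and set-25, both on III, which encode histone H3 lysine 9 methyltransferases. The genotypes were N2, lin-61, nrde-3, and the double mutants nrde-3 met-2, nrde-3 set-25, lin-61 met-2 and lin-61 set-25. The title of the series poses the question whether NRDE-3 and LIN-61 act in parallel pathways that recruit the methyltransferase of trimethylated lysine 9. The unit of measurement was the number of reads in each 500 bp window of the 6 nuclear chromosomes of build ce10, 200547 windows in all, without gene names. A window is named here by its chromosome and first base, and its level is given in TMM-normalised CPM as mean ± SD of 3 libraries.

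Libraries whose titles begin with 875 (N2 and lin-61) held more reads than those whose titles begin with 1121 (the other 5 genotypes). Totals were 54839178 to 67553226 reads in N2 and 59462797 to 66437115 in lin-61. They were 24343945 to 24651036 in nrde-3, 24300452 to 28834312 in nrde-3 met-2, 22275571 to 26088676 in nrde-3 set-25, 23861260 to 27564934 in lin-61 met-2 and 23900832 to 26549549 in lin-61 set-25. The mean correlation of log2 CPM within a genotype ran from 0.957 in nrde-3 met-2 to 0.993 in lin-61. A window of 0 reads over a genotype allows up to 3 reads, which is 0.0217 CPM in N2 and 0.0391 CPM in nrde-3. Such floors and the intervals given for ratios cover counting error only, since reads without molecular identifiers are not independent molecules. The labels speak of 2 independent biological replicates although the titles number 3, so p-values measure the spread between libraries, which need not be that between independent cultures.

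Before the comparisons, the labels were checked against windows lost in whole genotypes. Among 126 ways to split the 7 genotypes, 0 windows were lost in exactly the genotypes whose labels carry lin-61, nrde-3, met-2 or set-25, at a level of at least 5 CPM in every other library and at most 0.25 of it in the low ones. Windows that set other groups of genotypes apart were 25 low in all 5 genotypes of prefix 1121, 15 high in lin-61 alone, with N2 among the low ones, 6 low in the nrde-3 genotypes and lin-61 met-2, 3 in lin-61 and lin-61 set-25, and 3 in the 4 double mutants. Of the 6, all but X 372001 lay on I, from 7153501 to 7156500, away from the chromosome of nrde-3. The stretches that follow come from the last 3 of the patterns. On I, 7249001 to 7251000 held 123 ± 4.55 CPM in N2, 12.7 ± 0.0843 CPM in lin-61 and 15.7 ± 1.97 CPM in lin-61 set-25, but 132 ± 10.6 CPM in the libraries labelled lin-61 met-2. On X, 372001 to 377000 held 531 ± 42.8 CPM in N2, 73.2 ± 10.6 CPM in nrde-3, 54.7 ± 4.76 CPM in nrde-3 met-2, 61.5 ± 7.64 CPM in nrde-3 set-25 and 63.6 ± 7.21 CPM in the libraries labelled lin-61 met-2, against 455 ± 44.1 CPM in lin-61 and 347 ± 80.8 CPM in lin-61 set-25. On III, 13288001 to 13289000 held 38.7 ± 5.31 CPM in N2, 24.7 ± 3.12 CPM in nrde-3 and 30.3 ± 2.97 CPM in lin-61. There, 0 reads were found in nrde-3 set-25, lin-61 met-2 and lin-61 set-25 and 1 read in nrde-3 met-2, so the level in N2 was at least 1010-fold higher than in nrde-3 set-25, at least 1030-fold higher than in lin-61 met-2 and at least 1150-fold higher than in lin-61 set-25. Background at the level of quiet windows would give 31.4 reads in nrde-3 met-2 there, and 0.802% of those windows held no read in its 3 libraries, so the falls given for this stretch are not told apart from absent sequence. These stretches were chosen after the values were seen. All groups below carry the names of their labels, which these stretches contradict in the lin-61 met-2 libraries on I and X. On III, the met-2 and set-25 labels share the same loss, and 0 windows were lost in either label alone. The stretches therefore do not separate these labels, and the met-2 label of nrde-3 met-2 is in doubt as well.

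**Figure D1:**
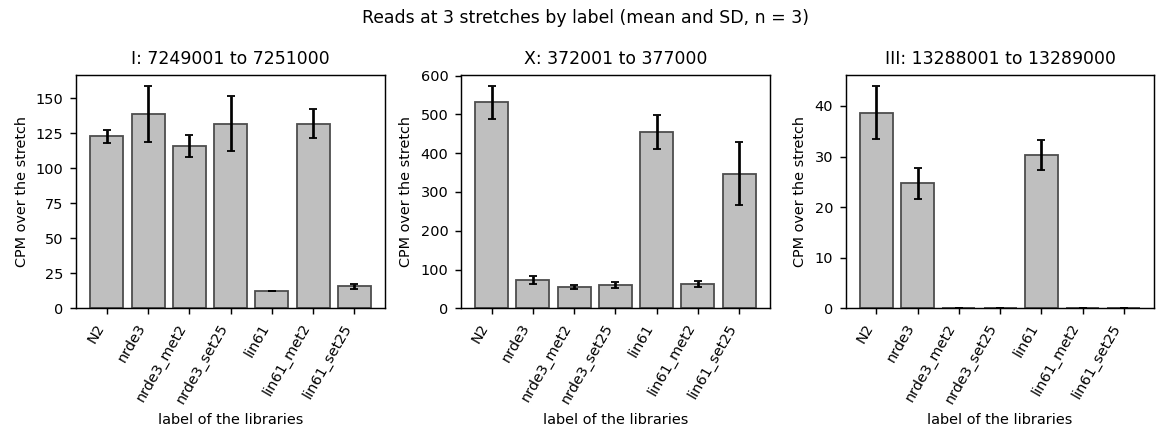
Level in 3 stretches of chromosomes I, X and III, in CPM by labelled genotype, with bars for the mean and error bars for the SD of 3 libraries. The lin-61 met-2 libraries lie near N2 on I (132 against 123 CPM), near nrde-3 on X (63.6 against 73.2 CPM) and at 0 reads on III.

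Loss of lin-61 alone raised far more windows than it lowered. Of 97353 windows tested, 10207 were higher and 1999 lower in lin-61 than in N2 at an adjusted p below 0.05, and 9420 of the higher ones rose by at least 2-fold. The windows that rose were nearly silent in N2, with a median of 0.34 CPM there against 1.27 CPM for all tested windows, and 23.4% of them lay on X against 15.8% of tested windows. The highest change was at X 4354501, with 919 reads in lin-61 and 2 in N2, a log2 fold change of 8.32 ± 0.85 (SE, adjusted p = 1.31e-06). V 17571001 rose from 0.743 ± 0.194 to 108 ± 15.4 CPM, a log2 fold change of 7.18 ± 0.33 (adjusted p = 8.24e-13), as part of a called region of 5 kb. V 4647501 rose from 0.299 ± 0.306 to 22.5 ± 13 CPM, a log2 fold change of 6.22 ± 0.72 (adjusted p = 7.15e-06). V 12378001, V 13415501 and V 8828001 rose by 6.2, 6.18 and 6.17 on the log2 scale, and V 13411001 held 213 reads against 1 in N2, a ratio of 189 (exact binomial 95% interval 33.6 to 7520).

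Among the windows that were lower in lin-61, I 7249001 fell from 41.6 ± 1.08 to 3.43 ± 0.416 CPM, a log2 fold change of -3.6 ± 0.22 (adjusted p = 1.25e-10). V 7761001 fell from 7.5 ± 1.76 to 1.03 ± 0.11 CPM, and II 4755001 from 18.6 ± 3.65 to 3.4 ± 0.344 CPM, log2 fold changes of -2.87 and -2.45. IV 2782001, I 1371001 and X 7301501 fell by 2.44, 2.17 and 1.95 on the log2 scale. IV 2829001, with 5 reads in lin-61 and 77 in N2, had the lowest log2 fold change, -3.99, at an adjusted p of 0.0471. That call was lost without N2 replicates a or c, without any 1 of the lin-61 libraries, or with background subtracted, at log2 fold changes of -4.21 and -3.37, of -3.79, -4.19 and -4.1, and of -3.99. For lin-61 against N2, higher and lower windows numbered 7022 and 856 without N2 replicate a, 4424 and 358 without N2 replicate c, 6311 and 583 without lin-61 replicate a, 9059 and 1219 without lin-61 replicate b, and 5809 and 388 without lin-61 replicate c. They numbered 11250 and 1046 with no filter on low counts, 16135 and 6245 with only these libraries fitted, and 10890 and 3716 with DESeq2. Both groups share the prefix 875.

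In nrde-3, 3838 windows were higher and 8027 lower than in N2, across the prefixes. The balance was opposite to that of lin-61, but not in the additive model with a prefix term (1880 higher and 163 lower). The windows that fell had a median of 12.1 CPM in N2, against 1.27 CPM for all tested windows. X 372001 fell from 81.1 ± 11 to 3.03 ± 1.15 CPM, a log2 fold change of -4.75 ± 0.31 (adjusted p = 8.7e-10), within the stretch of 5 kb described above. I 109001 fell from 179 ± 10.8 to 15.9 ± 2.19 CPM, a log2 fold change of -3.5 ± 0.2 (adjusted p = 4.8e-10), and it was low in every genotype of prefix 1121 (11.2 to 15.9 CPM) and high in lin-61 (171 ± 16 CPM). I 12486001, I 7156001, V 18968001, V 14358501 and I 3798501 fell by 3.55, 3.48, 3.47, 3.31 and 3.3 on the log2 scale. Of these, I 7156001 stayed at 9.38 ± 0.616 CPM in lin-61 set-25, while the other 4 were below 1 CPM in all 5 genotypes of prefix 1121.

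The windows with the largest rise in nrde-3 were near 0 in N2. X 4354501 held 86 reads in nrde-3 against 2 in N2, a ratio of 77.4 (20.8 to 650), at 1.12 ± 0.0733 CPM against 5.81 ± 3.17 CPM in lin-61. V 12378001 and V 4648001 rose by 4.5 and 3.87 on the log2 scale, and X 4925501 and II 7531001 by 3.91 and 3.88. IV 8314501 rose from 0.0529 ± 0.0365 to 4.21 ± 1.14 CPM, a log2 fold change of 6.26 ± 0.9 (adjusted p = 4.52e-05). X 15619501 rose by 4.53 on the log2 scale with 17 to 579 reads per library, and this call was lost without nrde-3 replicate a. N2 and nrde-3 differ in prefix, so that genotype and prefix cannot be told apart within this pair. In a model with additive terms for the mutations and the prefix, 1880 windows were higher and 163 lower with the nrde-3 term, X 15619501 and I 3798501 changed sign (-0.87 and 0.44), and the calls at IV 8314501, I 12486001, I 109001, I 7156001, V 18968001 and V 14358501 were lost, at log2 fold changes of 1.19, -0.59, -0.2, -1.89, -0.87 and -0.27. For nrde-3 against N2, higher and lower windows numbered 2080 and 6431 without N2 replicate a, 1871 and 6571 without N2 replicate b, 1152 and 5415 without N2 replicate c, 2361 and 7109 without nrde-3 replicate a, and 1664 and 5645 without nrde-3 replicate b. They numbered 2536 and 8124 with no filter on low counts.

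Most windows called in nrde-3 met-2 against nrde-3 were higher, from a near-silent level in nrde-3. In nrde-3 met-2, 6492 windows were higher and 811 lower than in nrde-3, within prefix 1121. The higher windows had a median of 0.0736 CPM in nrde-3 and a median log2 fold change of 3.04. That median lies below the background of the nrde-3 met-2 libraries in quiet windows, 0.0989 to 0.298 CPM per window. Of the 7303 windows called, 2152 were also called with background subtracted and 2715 with only these libraries fitted. At III 5356001, 12430 reads in nrde-3 met-2 faced 9 in nrde-3, a log2 fold change of 10.28 ± 1.38 (adjusted p = 4.67e-05), with 123 to 8467 reads per library. X 11787001 rose from 0.433 ± 0.142 to 320 ± 327 CPM and I 3664501 from 0.0643 ± 0.0189 to 49.7 ± 49.2 CPM, log2 fold changes of 9.52 and 9.5. V 17309001 and X 4026001 had ratios of 983 (272 to 8120) and 966 (173 to 38200) over 2 and 1 reads in nrde-3. All 5 windows were lowest in nrde-3 met-2 replicate b. III 1301001, with 4434 reads against 3, had a ratio of 1350 (463 to 6560) and was highest in replicate b, with 2622 reads. X 9187001 was closer among the libraries, at 15.2 ± 6.01 CPM and a ratio of 1150 (207 to 45600).

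Of the windows that fell in nrde-3 met-2, III 13288501 held 0 reads against 569 in nrde-3, at least 207-fold lower (adjusted p = 1.89e-08). IV 8609001 fell from 6.66 ± 0.568 to 1.33 ± 0.537 CPM, a log2 fold change of -2.32 ± 0.29 (adjusted p = 2.91e-05). III 12215001, IV 1981501, IV 16862001, IV 8075501 and III 1870001 fell by 1.3, 1.3, 1.2, 1.2 and 1.2 on the log2 scale, calls that were all lost when the 6 libraries were fitted alone, with log2 fold changes of -1.26, -1.2, -1.18, -1.17 and -1.17. The calls at IV 1981501, IV 8075501 and III 1870001 were also lost without nrde-3 met-2 replicate a (log2 fold changes of -1.17, -1.01 and -0.88) and with background subtracted (-1.23, -1.07 and -1.24, at adjusted p of 0.0548, 0.0884 and 0.0699). In 32179 windows with at most 2 reads over all N2 and lin-61 libraries, the nrde-3 met-2 libraries held 0.0989 to 0.298 CPM per window, against 0.00491 to 0.00586 CPM in nrde-3. For nrde-3 met-2 against nrde-3, higher and lower windows numbered 11836 and 3490 without nrde-3 replicate a, 12183 and 2290 without nrde-3 replicate b, 10784 and 1597 without nrde-3 replicate c, 5428 and 456 without nrde-3 met-2 replicate a, 18226 and 4971 without nrde-3 met-2 replicate b, and 4419 and 2341 without nrde-3 met-2 replicate c. They numbered 45943 and 15924 with no filter on low counts, 2763 and 12 with only these libraries fitted, 7081 and 1852 with DESeq2, and 2043 and 551 with background subtracted.

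**Figure D2:**
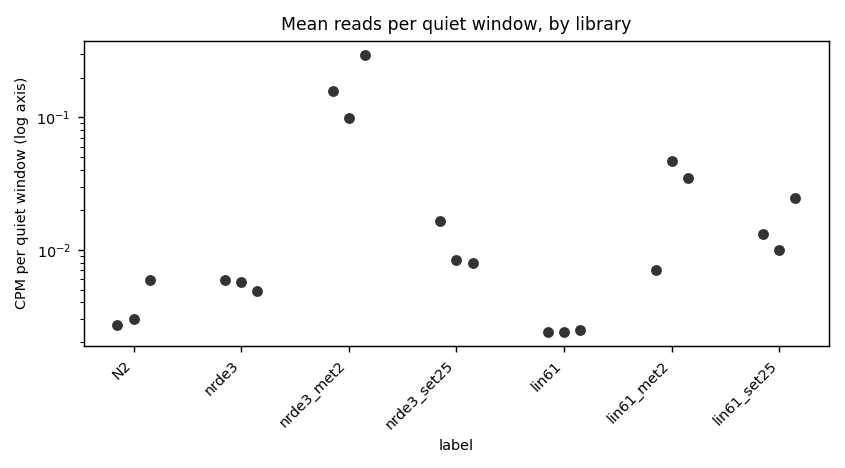
Reads per window in CPM in 32179 windows with at most 2 reads over the 6 libraries of prefix 875, for each of the 21 libraries. The 3 nrde-3 met-2 libraries lie at 0.157, 0.0989 and 0.298 CPM, above all other libraries, of which the highest is lin-61 met-2 replicate b at 0.047 CPM.

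In nrde-3 set-25, 2392 windows were higher and 226 lower than in nrde-3. The windows at the top of the list were near 0 in both N2 and nrde-3. II 8358501 held 164 reads against 0 in nrde-3, at least 53.5-fold higher (adjusted p = 0.00216). V 12404001 held 237 reads against 1, a ratio of 232 (41.2 to 9190). I 11489501 had a ratio of 129 (44 to 630) and IV 8825501 of 131 (35.8 to 1080), each over 2 or 3 reads in nrde-3. IV 11226001 rose by 6.44 ± 0.96 on the log2 scale. IV 4516501 rose from 0.0655 ± 0.0238 to 4.66 ± 2.11 CPM, a log2 fold change of 6.09 ± 0.74 (adjusted p = 9.23e-05). V 8828001, one of the windows with the largest rise in lin-61, reached 1.08 ± 0.495 CPM, a ratio of 80.2 (14 to 3210).

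Of the 7 lower windows named in nrde-3 set-25, 4 lay on III. Apart from III 4172501, these lay in or near the III stretch described above. III 13288001 held 0 reads against 1322, at least 451-fold lower (adjusted p = 6.29e-10). III 13291001 fell from 13.7 ± 5.37 to 3.94 ± 0.151 CPM and III 13284001 from 11 ± 3.09 to 3.51 ± 0.272 CPM, log2 fold changes of -1.79 and -1.66. IV 8609001 fell by 2.58 on the log2 scale. III 4172501, I 6222501 and II 7218001 fell by 1.58, 1.55 and 1.45, and these 3 calls were lost without nrde-3 replicate c, nrde-3 set-25 replicate a or nrde-3 set-25 replicate c. Their log2 fold changes were then -1.07, -1.565 and -1.024, -1.503, -1.505 and -1.253, and -1.551, -1.607 and -1.514. I 6222501 was also lost without nrde-3 replicate a or nrde-3 set-25 replicate b, at -1.307 and -1.548. For nrde-3 set-25 against nrde-3, higher and lower windows numbered 989 and 324 without nrde-3 replicate a, 1423 and 122 without nrde-3 replicate b, 481 and 20 without nrde-3 replicate c, 663 and 29 without nrde-3 set-25 replicate a, 1766 and 60 without nrde-3 set-25 replicate b, and 1454 and 60 without nrde-3 set-25 replicate c. They numbered 3667 and 239 with no filter on low counts, and 3391 and 630 with DESeq2.

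The libraries labelled lin-61 met-2 had 5702 windows higher and 9218 lower than lin-61. The windows with the largest rise came from replicates b and c. V 16707001 held 1 read in replicate a, 444 in b and 845 over the group, against 0 in lin-61, at least 547-fold higher over the group (adjusted p = 0.00496). III 1302501 held 2075 reads against 1, a ratio of 4030 (722 to 159000), of which 3 were in replicate a. III 3335501 and V 3099001 had ratios of 2160 (387 to 85300) and 866 (155 to 34300), and II 5145501 rose by 8.26 ± 1.3 on the log2 scale, with 5, 1 and 3 reads in replicate a. II 13985001 and III 931001 rose by 9.1 and 7.99 on the log2 scale, with 9 reads each in replicate a. All 7 windows had a higher mean in nrde-3 met-2 than in the libraries labelled lin-61 met-2, for example 138 ± 42.6 against 25.6 ± 22.3 CPM at III 931001.

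Some of the windows that fell most were ones at which lin-61 stood above the other 6 genotypes. V 17571001 fell from 108 ± 15.4 to 1.21 ± 0.58 CPM, a log2 fold change of -6.46 ± 0.32 (adjusted p = 5.12e-12). IV 5686001 fell from 10.3 ± 1.39 to 0.295 ± 0.102 CPM, near its 0.287 ± 0.0566 CPM in N2. III 13288001 held 0 reads against 3285, at least 564-fold lower. X 372001 fell by 4.7 on the log2 scale, I 532501 by 4.05 and V 14112001 by 3.88. I 15066501, in the outermost part of the chromosome, fell from 21100 ± 3660 to 844 ± 181 CPM, a log2 fold change of -4.64 ± 0.7 (adjusted p = 5.93e-05). Libraries of 1 genotype differed widely there, at 8330, 593 and 1040 CPM in nrde-3, so its level does not follow genotype alone. The groups differ in prefix, and genotype and prefix cannot be told apart for this pair. For lin-61 met-2 against lin-61, higher and lower windows numbered 2662 and 7393 without lin-61 replicate a, 2635 and 6606 without lin-61 replicate b, 2362 and 7000 without lin-61 replicate c, 3315 and 6971 without lin-61 met-2 replicate b, and 2667 and 6239 without lin-61 met-2 replicate c. They numbered 10910 and 14672 with only these libraries fitted.

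In lin-61 set-25, 13084 windows were higher and 12970 lower than in lin-61. V 12404001 and II 8358501, which rose in nrde-3 set-25, also rose here, at higher levels. V 12404001 rose from 0.037 ± 0.036 to 21.6 ± 21.6 CPM, a log2 fold change of 9 ± 0.75 (adjusted p = 1.25e-08), against 3.04 ± 0.942 CPM in nrde-3 set-25. II 8358501 rose from 0.0308 ± 0.0371 to 16.6 ± 16.9 CPM, a log2 fold change of 8.86 ± 0.83 (adjusted p = 2.23e-07), with 120 to 1092 reads per library. A further 5 windows rested on replicate a: V 16707001, III 3336501, III 1301501, II 13985001 and V 3099001 held 340, 667, 381, 900 and 187 reads there, and each of these calls was lost without it. The first was at least 216-fold higher over 0 reads in lin-61. The second, the third and V 3099001 had ratios of 1200 (214 to 47400), 680 (121 to 26900) and 335 (59.5 to 13300) over 1 read, and II 13985001 rose by 8.44 on the log2 scale.

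The falls in lin-61 set-25 were more even among the libraries. III 13288001 held 0 reads against 3285, at least 627-fold lower. III 5020501 fell from 11.5 ± 2.06 to 0.457 ± 0.15 CPM, a log2 fold change of -4.63 ± 0.32 (adjusted p = 1.67e-09), and I 10227501 from 69.5 ± 15.1 to 3.24 ± 0.822 CPM. II 4755001, already lower in lin-61 than in N2, fell further from 3.4 ± 0.344 to 0.149 ± 0.0482 CPM. V 14112001, II 12194501 and II 12992501 fell by 4.56, 4.38 and 4.32 on the log2 scale. Apart from III 13288001, these windows were also low in nrde-3, for example 6.14 ± 0.588 CPM at I 10227501 against 54.5 ± 8.22 CPM in N2. The groups differ in prefix, as above. For lin-61 set-25 against lin-61, higher and lower windows numbered 9079 and 10680 without lin-61 replicate a, 7718 and 9426 without lin-61 replicate b, 9012 and 10633 without lin-61 replicate c, and 6801 and 10181 without lin-61 set-25 replicate c. They numbered 11218 and 13937 with no filter on low counts, 10652 and 13061 with only these libraries fitted, and 11662 and 11975 with background subtracted.

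**Figure D3:**
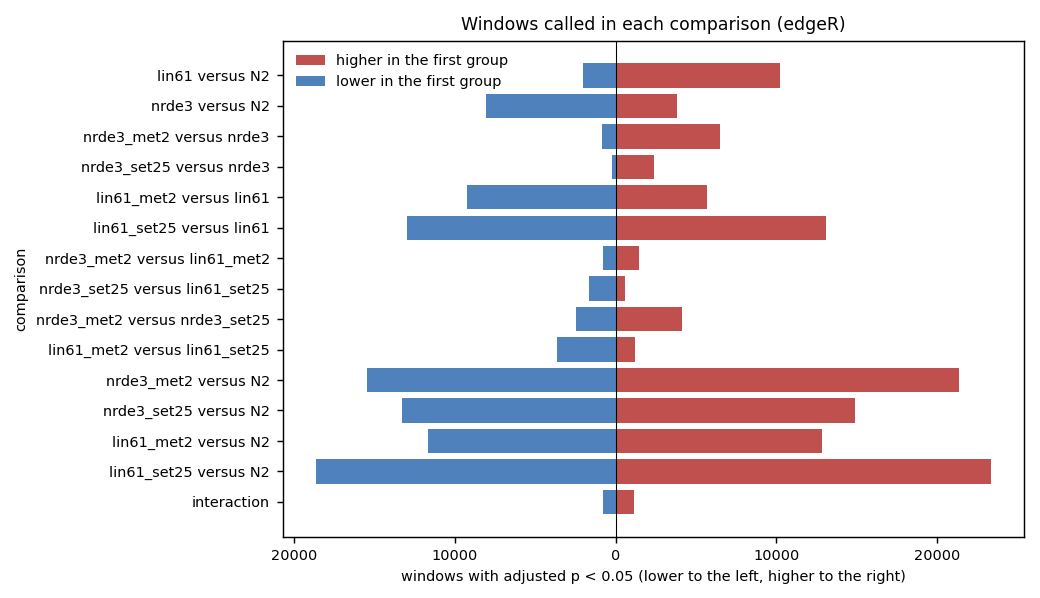
Numbers of 500 bp windows called higher (to the right) and lower (to the left) at an adjusted p below 0.05 in each comparison, out of 97353 tested. The count was highest for lin-61 set-25 against N2 (23321 higher, 18597 lower).

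**Figure D4:**
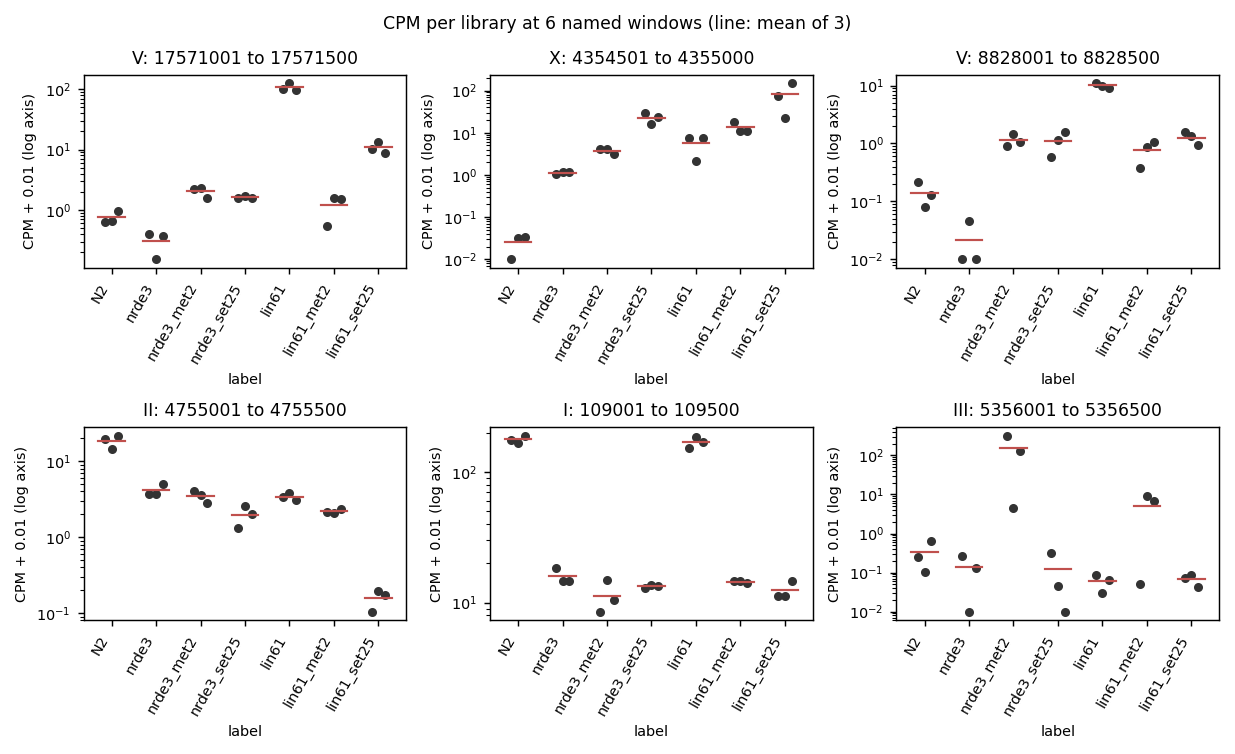
Level of each library in 6 named windows, in CPM on a log axis, by labelled genotype. V 17571001 was at 108 CPM in lin-61 and at most 10.9 CPM in the mean of any other genotype, while X 4354501 ran from 0.0157 CPM in N2 to 81.7 CPM in lin-61 set-25.

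Between the double mutants, which share the prefix 1121, the comparison within the set-25 label asks whether the partner mutation matters. Nrde-3 set-25 had 596 windows higher and 1623 lower than lin-61 set-25. The windows that were lower included X 372001 (3.9 ± 1.12 against 50.2 ± 15.1 CPM), X 6323501 (1.75 ± 0.369 against 18.4 ± 15.5 CPM) and IV 5686001 (0.128 ± 0.0184 against 1.29 ± 0.357 CPM), at adjusted p of 4.92e-08, 0.000141 and 0.000151. Those that were higher included II 4755001 (1.97 ± 0.651 against 0.149 ± 0.0482 CPM), I 7249501 (38.1 ± 5.2 against 3.46 ± 0.15 CPM) and V 13556501 (3.64 ± 0.316 against 0.47 ± 0.192 CPM). X 372001 and I 7249501 lie in the stretches on X and I described above, which were chosen by their levels in these genotypes. They are therefore no separate sign that the partner mutation matters. For nrde-3 set-25 against lin-61 set-25, higher and lower windows numbered 192 and 348 without nrde-3 set-25 replicate b, 176 and 393 without nrde-3 set-25 replicate c, 1063 and 5036 without lin-61 set-25 replicate b, and 171 and 295 without lin-61 set-25 replicate c. They numbered 563 and 2574 with no filter on low counts, 66 and 96 with only these libraries fitted, and 1024 and 2653 with DESeq2.

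Within the met-2 label, nrde-3 met-2 had 1432 windows higher and 783 lower than the libraries labelled lin-61 met-2. IV 11071001 (82.7 ± 74.1 against 2.93 ± 1.98 CPM), V 12510001 (33.7 ± 27.6 against 1.19 ± 0.931 CPM) and IV 5691001 (24.8 ± 21.2 against 1.03 ± 0.696 CPM) were the highest, at adjusted p of 0.00701, 0.0028 and 0.00772. II 7911001 (2.75 ± 1.15 against 20.1 ± 5.9 CPM), X 4353501 (2.68 ± 0.081 against 17.3 ± 5.3 CPM) and II 5831001 (8.26 ± 1.5 against 38.3 ± 20.5 CPM) were lower, at adjusted p of 0.0177, 0.0102 and 0.0228. The calls at IV 11071001, IV 5691001, II 7911001, X 4353501 and II 5831001 were lost without lin-61 met-2 replicate a. Apart from X 4353501, the 6 windows also lost their calls when the 6 libraries were fitted alone, each at an adjusted p of 0.0736 and with log2 fold changes of 4.86, 4.85, 4.62, -2.82 and -2.17. Which direction had more windows changed with the setting. For nrde-3 met-2 against lin-61 met-2, higher and lower windows numbered 1009 and 513 without nrde-3 met-2 replicate a, 6479 and 1500 without nrde-3 met-2 replicate b, 1737 and 2015 without nrde-3 met-2 replicate c, 5 and 1 without lin-61 met-2 replicate a, 693 and 272 without lin-61 met-2 replicate b, and 526 and 583 without lin-61 met-2 replicate c. They numbered 5424 and 7193 with no filter on low counts, 0 and 1 with only these libraries fitted, and 1857 and 1515 with DESeq2.

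Replacing the set-25 label by met-2 in the nrde-3 background gave 4132 windows higher and 2429 lower. III 5355501, X 11786001 and I 3666001 rose by 10.63, 10.15 and 9.46 on the log2 scale, at 107 ± 118, 62 ± 66.3 and 38.4 ± 40.4 CPM in nrde-3 met-2 (adjusted p of 9.16e-05, 9.4e-05 and 9.48e-05). II 7911001, X 4353501 and II 5831001 were lower by -3.6, -3.3 and -3.0 on the log2 scale, at 32.5 ± 9.9, 26.8 ± 3.31 and 68.1 ± 27.4 CPM in nrde-3 set-25. For nrde-3 met-2 against nrde-3 set-25, higher and lower windows numbered 12038 and 3845 without nrde-3 met-2 replicate b, 4486 and 3835 without nrde-3 met-2 replicate c, and 7873 and 3628 without nrde-3 set-25 replicate a. They numbered 29659 and 14730 with no filter on low counts, and 2481 and 1079 with only these libraries fitted.

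In the lin-61 background the same replacement gave 1227 windows higher and 3655 lower. IV 11226001 (0.646 ± 0.154 against 12.9 ± 10.8 CPM), X 372001 (2.91 ± 0.698 against 50.2 ± 15.1 CPM) and II 8358501 (1.04 ± 0.222 against 16.6 ± 16.9 CPM) were lower in the libraries labelled lin-61 met-2, at adjusted p of 2.36e-05, 8.44e-09 and 0.000574. V 17308501 held 88 reads against 0, at least 32.6-fold higher, I 3664501 had a ratio of 194 (34.4 to 7720) and III 5355001 rose by 7.16 on the log2 scale, and these 3 calls were lost without lin-61 set-25 replicate c, at fitted log2 fold changes of 8.17, 6.67 and 7.04, from 8.17, 7.15 and 7.16. For lin-61 met-2 against lin-61 set-25, higher and lower windows numbered 820 and 2065 without lin-61 met-2 replicate a, 519 and 1640 without lin-61 met-2 replicate b, 463 and 1107 without lin-61 met-2 replicate c, 1749 and 7867 without lin-61 set-25 replicate b, and 251 and 625 without lin-61 set-25 replicate c. They numbered 145 and 370 with only these libraries fitted. A comparison added after the data were seen set the libraries labelled lin-61 met-2 against nrde-3 set-25. There edgeR called 0 of 97353 windows, with 2432 at an unadjusted p below 0.05 and a smallest adjusted p of 0.429. DESeq2 called 0, and edgeR on these 6 libraries alone called 0.

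Against N2, a comparison that crosses the prefixes, each double mutant had more windows called than nrde-3 had. Nrde-3 met-2 had 21378 higher and 15479 lower, nrde-3 set-25 had 14873 and 13264, the libraries labelled lin-61 met-2 had 12865 and 11638, and lin-61 set-25 had 23321 and 18597. X 4354501, at 2 reads in N2, had a ratio of 1580 (436 to 13000) in nrde-3 set-25, 906 (250 to 7490) in lin-61 met-2 and 5800 (1610 to 47900) in lin-61 set-25. II 8358501, at 0 reads in N2, was at least 96.3-fold, 47.8-fold and 782-fold higher in the same genotypes. II 8446501 had a ratio of 428 (146 to 2080) in nrde-3 set-25, and V 12404001 one of 3070 (550 to 121000) in lin-61 set-25. In nrde-3 met-2, V 16709001 and V 658001 had ratios of 12000 (2160 to 475000) and 1500 (414 to 12400), and II 13985001 rose by 10.45 on the log2 scale, with replicate b far above the others. V 16707001 had a ratio of 729 (201 to 6030) in lin-61 met-2, with 1 read in replicate a.

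Windows below N2 in the double mutants included the III stretch, where III 13288501 was at least 371-fold lower in nrde-3 met-2 and III 13288001 at least 654-fold, 667-fold and 741-fold lower in nrde-3 set-25, lin-61 met-2 and lin-61 set-25. X 372001 fell by 5.33 and 4.8 on the log2 scale in nrde-3 met-2 and lin-61 met-2, and I 109001 by 4 in nrde-3 met-2. V 18968001 fell by 4.7 in nrde-3 set-25, and II 4755001 by 6.95 in lin-61 set-25. V 17117501, at 822 to 8953 reads per library in N2, fell by 4.38 in nrde-3 set-25 and 3.97 in lin-61 met-2. V 17308501 held 0 reads against 31 in lin-61 set-25, at least 6.65-fold lower at an adjusted p of 0.0491, a call lost with RLE scaling, with background subtracted, without N2 replicate c and without any 1 of the lin-61 set-25 libraries. Its fitted log2 fold change was -5.96, and -5.95, -5.92, -4.99, -5.98, -5.99 and -5.98 in these settings. In the additive model V 17117501 changed sign (1.42 and 1.78). The additive model also ended calls, at fitted log2 fold changes given here with those of the first model: III 13288501 in nrde-3 met-2 (-11.51 from -11.8), II 8358501 in nrde-3 set-25 (10.59 from 9.1) and lin-61 met-2 (9.69 from 8.12) and III 13288001 in nrde-3 set-25 (-10.52 from -12.72). It ended those at V 16709001 (10.17 from 12.95), V 658001 (8.32 from 10.22), II 13985001 (5.99 from 10.45) and I 109001 (-0.57 from -4) in nrde-3 met-2, V 18968001 in nrde-3 set-25 (-1.89 from -4.7), V 16707001 (4.61 from 9.12) and X 372001 (-1.45 from -4.8) in lin-61 met-2, and V 17308501 in lin-61 set-25 (-2.1 from -5.96). Where a group has 0 reads, such fitted values depend on the prior count. For nrde-3 met-2 against N2, higher and lower windows numbered 66190 and 29535 with no filter on low counts, 5731 and 1166 with the additive model, and 12592 and 12601 with background subtracted. For nrde-3 set-25 against N2, higher and lower windows numbered 12130 and 12422 without N2 replicate b, 9113 and 9990 without N2 replicate c, and 9395 and 9029 without nrde-3 set-25 replicate a. They numbered 7146 and 893 with the additive model. For lin-61 met-2 against N2, higher and lower windows numbered 8700 and 10096 without N2 replicate a, 9738 and 11138 without N2 replicate b, 6728 and 8893 without N2 replicate c, and 8239 and 8669 without lin-61 met-2 replicate b. They numbered 12259 and 12754 with no filter on low counts, and 11694 and 3020 with the additive model. For lin-61 set-25 against N2, higher and lower windows numbered 15074 and 5871 with the additive model.

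The interaction asked whether the difference between the met-2 and set-25 labels depends on the partner mutation. It was called in 1173 windows where the difference was more positive with nrde-3 and in 749 where it was more negative. IV 11071001, IV 5691001 and V 12510001 had the highest interaction terms (5.55 ± 1.03, 4.98 ± 1.18 and 4.71 ± 1.09 on the log2 scale). The lowest were at I 7249001 (-3.64 ± 0.29), II 3596001 (-3.22 ± 0.52) and II 4755001 (-3.05 ± 0.44). Adjusted p were 0.00882, 0.0325, 0.0282, 2.39e-07, 0.00301 and 0.000879. I 7249001 lies in the stretch on I that was chosen by its level in these genotypes. In that stretch the lin-61 met-2 libraries contradict their label, so its term is no separate sign of an interaction. The calls at IV 5691001 and V 12510001 were lost under background subtraction, with the 12 libraries fitted alone, and without any 1 of nrde-3 set-25 replicates b and c, lin-61 met-2 replicate a, or lin-61 set-25 replicates a and c. IV 5691001 was also lost without nrde-3 met-2 replicate a or lin-61 met-2 replicate c. Their interaction terms were 5.18 and 4.91 with background subtracted (adjusted p of 0.0554 and 0.0509) and 5.01 and 4.74 with the 12 libraries fitted alone (0.0584 and 0.0739), no smaller than in the fit of all libraries. Which direction had more windows changed with the setting. For the interaction, higher and lower windows numbered 2348 and 1089 without nrde-3 met-2 replicate b, 1185 and 1930 without nrde-3 met-2 replicate c, 1222 and 1415 without nrde-3 set-25 replicate a, 226 and 166 without nrde-3 set-25 replicate b, 267 and 173 without nrde-3 set-25 replicate c, 250 and 178 without lin-61 met-2 replicate a, 671 and 426 without lin-61 met-2 replicate b, 645 and 704 without lin-61 met-2 replicate c, 652 and 414 without lin-61 set-25 replicate a, 3497 and 2267 without lin-61 set-25 replicate b, and 366 and 375 without lin-61 set-25 replicate c. They numbered 2420 and 3454 with no filter on low counts, 214 and 95 with only these libraries fitted, 2369 and 1683 with DESeq2, and 252 and 194 with background subtracted.

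For each methyltransferase label, the changes in the nrde-3 and lin-61 backgrounds were compared across windows, which are not independent replicates. Among the windows that rose with the set-25 label in nrde-3, 1311 of 2392 also rose in lin-61, where independent calls would give 321.5, and 68 of 226 fell in both, where independent calls would give 30.11. Pearson's r over all tested windows was 0.453 and Spearman's rho 0.284. For the met-2 label, 969 of 6492 rose in both (380.2 for independent calls) and 82 of 811 fell in both (76.79), with r = 0.385 and rho = 0.0895. Calls went the opposite way in lin-61 for 289 of the 6492 and 74 of the 811. With the set-25 label they did so for 94 of the 2392 and 8 of the 226. The comparisons share no library, but that in lin-61 crosses the prefixes. For the met-2 label, that in lin-61 also rests on the lin-61 met-2 libraries, whose label the stretches on I and X contradict. If that label is wrong, r, rho and the shared calls for met-2 do not compare its loss in nrde-3 with its loss in lin-61. The r for set-25 was 0.229 without lin-61 set-25 replicate c and 0.301 without nrde-3 set-25 replicate a. That for met-2 was 0.579 without lin-61 met-2 replicate a and 0.301 with background subtracted. The filter on low counts was rerun in these fits, so the windows behind r also changed.

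The arms of the autosomes, taken as the outer parts when each chromosome is divided into 3 equal parts, hold much of the repeated sequence and H3K9 methylation in this species. They held 62.6% of the tested autosomal windows. Of the windows higher in nrde-3 than in N2, 52.5% lay in the arms, and of those lower, 68.2% (adjusted p = 0.012 each, permutation by 1000 circular rotations, 2-sided, adjusted over 30 comparisons, from the smallest p that these rotations can give, 0.002). Of the windows higher in lin-61 than in N2, 56.6% lay in the arms (adjusted p = 0.14 by the same permutation). Against N2, the share of higher windows in the arms was 56.2% in nrde-3 met-2, 53.3% in nrde-3 set-25, 54.1% in lin-61 met-2 and 57% in lin-61 set-25 (adjusted p of 0.012, 0.017, 0.017 and 0.055 by permutation), and that of lower windows 63.9, 66, 65.3 and 63.6% (0.35, 0.027, 0.054 and 0.5). Against lin-61, 58.5% of the windows higher and 69.2% of those lower in lin-61 met-2 lay there, and 56.3% and 65.1% in lin-61 set-25 (adjusted p of 0.09, 0.012, 0.027 and 0.14 by permutation). Each of these comparisons, apart from lin-61 against N2, crosses the prefixes. Within prefix 1121, 56.3% of the windows lower in nrde-3 met-2 than in nrde-3 set-25 lay in the arms (adjusted p = 0.012 by permutation). The share in the arms of windows higher in nrde-3 met-2 than in nrde-3 was 61.8%, and of those higher in nrde-3 set-25 than in nrde-3 57.7% (adjusted p of 0.86 and 0.35 by permutation).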

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

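The tests of background reads given here were chosen after the result was seen, and the regrouping of the libraries was planned before.

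The interaction between the methyltransferase label and the partner mutation was called in 1922 windows, and stands here because it is a tested difference between groups in the response to the same change. Its named windows were IV 11071001 (5.55 on the log2 scale), IV 5691001 (4.98), V 12510001 (4.71), I 7249001 (-3.64), II 3596001 (-3.22) and II 4755001 (-3.05). With the 12 libraries of the 4 double mutants fitted alone, the interaction was called in 309 windows, and of 60 groupings of these libraries, the real one included, 1 gave as many. The highest other grouping gave 19. These groupings mixed libraries of all 4 genotypes. They ask whether the genotypes differ at all, so they cannot exclude chance as the source of the interaction. The count of 1922 was 392 and 440 without nrde-3 set-25 replicates b and c, 428 and 1097 without lin-61 met-2 replicates a and b, 1066, 5764 and 741 without lin-61 set-25 replicates a, b and c, and 3437 and 3115 without nrde-3 met-2 replicates b and c. Because the stretches on I and X contradict the lin-61 met-2 label, the interaction does not measure what its terms are named for if that label is wrong. The stretch on III leaves the met-2 label of nrde-3 met-2 in doubt as well.

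The nrde-3 met-2 libraries held reads in windows with at most 2 reads over all N2 and lin-61 libraries, 0.157, 0.0989 and 0.298 CPM per window in replicates a, b and c, against 0.00271 to 0.00593 CPM in N2 and 0.00491 to 0.00586 CPM in nrde-3. Spread over the genome, this level would make up 3.34, 1.92 and 7.27% of the reads, and 82, 76.2 and 98.3% of these 32179 windows held a read. Genomic DNA should lie evenly, with a ratio of arms over centre between 0.8 and its inverse and the lowest chromosome at no less than 0.8 of the highest, but the ratio was 0.73, 1.11 and 0.817 and the highest chromosome 1.22, 1.48 and 1.09 times the lowest, so that only replicate c met both bounds, while replicate b, with a variance over mean of 1020 against 4.65 and 3.99 in a and c, can owe its ratios to a few windows, and lin-61 met-2 replicates b and c, raised to 0.047 and 0.0348 CPM, met both (0.907 and 0.91, 1.14 and 1.15). Transcription of silent windows in this genotype should give a like level in each library, but the highest was 3.01 times the lowest. DNA that passed the DNase step and transcription cannot be told apart, and both may contribute. The bounds for even DNA were met by replicate c only, and the value of 3.01 lay between those set for a like and an unlike level.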

How the results depend on the processing

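With RLE scaling, no count of windows moved by over 1.5 times. With no filter on low counts, the count was 61867 for nrde-3 met-2 against nrde-3, 12617 against lin-61 met-2, 44389 against nrde-3 set-25 and 95725 against N2, and 5874 for the interaction. For windows with an average log2 CPM of at least 1, r for set-25 was 0.348. With only the groups compared, the count was 22380 for lin-61 against N2, 2775 for nrde-3 met-2 against nrde-3, 25582 for lin-61 met-2 against lin-61, 1 for nrde-3 met-2 against lin-61 met-2, 162 for nrde-3 set-25 against lin-61 set-25, 3560 for nrde-3 met-2 against nrde-3 set-25, 515 for lin-61 met-2 against lin-61 set-25 and 309 for the interaction. DESeq2 called 4021 for nrde-3 set-25 against nrde-3, 3372 for nrde-3 met-2 against lin-61 met-2, 3677 for nrde-3 set-25 against lin-61 set-25 and 4052 for the interaction. The additive model with library prefix gave 2043 for nrde-3, 6897 for nrde-3 met-2, 8039 for nrde-3 set-25, 14714 for lin-61 met-2 and 20945 for lin-61 set-25, each against N2. It reversed X 15619501 (-0.87) and I 3798501 (0.44) in nrde-3 and V 17117501 in nrde-3 set-25 (1.42) and lin-61 met-2 (1.78), each against N2. Background subtraction, added after the data were seen, gave 2594 for nrde-3 met-2 against nrde-3, 446 for the interaction and r = 0.301 for met-2. The cause of these changes was not tested.

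Leaving out 1 library at a time, the count ran from 4782 to 10278 for lin-61 against N2, 6567 to 9470 for nrde-3 against N2, 31463 to 50459 for nrde-3 met-2 against N2, 18424 to 24552 for nrde-3 set-25 against N2, 15621 to 20876 for lin-61 met-2 against N2 and 30353 to 45676 for lin-61 set-25 against N2. It ran from 5884 to 23197 for nrde-3 met-2 against nrde-3, 501 to 1826 for nrde-3 set-25 against nrde-3, 8906 to 11373 for lin-61 met-2 against lin-61 and 16982 to 26434 for lin-61 set-25 against lin-61. It ran from 6 to 7979 for nrde-3 met-2 against lin-61 met-2, 466 to 6099 for nrde-3 set-25 against lin-61 set-25, 5702 to 15883 for nrde-3 met-2 against nrde-3 set-25, 876 to 9616 for lin-61 met-2 against lin-61 set-25 and 392 to 5764 for the interaction. The r for met-2 ran from 0.355 to 0.579 and that for set-25 from 0.229 to 0.426. Libraries whose removal moved the total, the higher or the lower windows of a comparison by over 1.5 times, or turned their balance, are named with their counts in the report, and why they did so was not tested. The filter on low counts was rerun with each library left out, so part of a shift can come from a changed set of tested windows. Of the values for named windows, 137 of 138 kept their direction and call with RLE scaling, 138 of 138 with no filter, 114 of 126 with only the groups compared, 137 of 137 with DESeq2, 16 of 38 with the additive model, 131 of 138 with background subtracted and 815 of 864 when leaving out 1 library.

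No paired analysis was possible because the columns carry letters that are not tied to the replicate numbers of the labels. The replicate block, tests of gene lists with a preset or an estimated correlation, and the alternatives for repeat families were therefore not run, the latter since the counts carry no gene or repeat names. On simulated data, over windows of all levels, 18 to 20 of 100 changes of 1 on the log2 scale were recovered, and 81 of 100 changes of 2. The simulation gave all genotypes the same spread, so these rates need not hold for the real libraries.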

Other observations

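The tests in this part were chosen after the results were seen, apart from the regroupings of libraries, which were planned.

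X 4354501 and V 4647501, near 0 in N2 and among the windows with the largest rise in lin-61, had means in the same order. At X 4354501 the level was 0.0157 CPM in N2, 1.12 in nrde-3, 3.76 in nrde-3 met-2, 5.81 in lin-61, 13.3 in the libraries labelled lin-61 met-2, 22.8 in nrde-3 set-25 and 81.7 in lin-61 set-25. V 4647501 ran in the same order of genotypes, at 0.299, 3.58, 12.5, 22.5, 41.2, 78.1 and 261 CPM. The order is one of means only, since libraries of neighbouring genotypes overlapped. At X 4354501, lin-61 replicate b (2.15 CPM) lay below every nrde-3 met-2 library (lowest 3.11 CPM). There, lin-61 set-25 replicate b (22.2 CPM) lay below nrde-3 set-25 replicates a and c (28.7 and 23.4 CPM). At V 4647501, lin-61 replicate b (9.51 CPM) and lin-61 set-25 replicate b (65.3 CPM) overlapped nrde-3 met-2 and nrde-3 set-25. The order also crosses the prefixes, and edgeR called 0 windows between the libraries labelled lin-61 met-2 and nrde-3 set-25. V 17571001 and V 8828001 differed, being highest in lin-61 (108 and 10 CPM) and lower in lin-61 set-25 (10.9 and 1.26 CPM). Windows that rise without lin-61 may also rise without set-25: of the 10207 windows higher in lin-61 than in N2, 96.8% had a higher estimate in nrde-3 set-25 than in nrde-3, against 49% of all windows, and 1771 were called higher in both, where independent calls would give 250.8. For met-2, 84.3% of them had a higher estimate in nrde-3 met-2 than in nrde-3, against 52.6% of all windows, and 1079 were called higher in both (680.7 for independent calls), but background reads in nrde-3 met-2 (0.0989 to 0.298 CPM in quiet windows, against 0.00491 to 0.00586 in nrde-3) would by themselves raise near-silent windows, so whether the overlap is particular to set-25 stays open. These comparisons share no library and each lies within 1 prefix. The shares over all windows are not matched for level. The 10207 windows had a median of 0.34 CPM in N2, against 1.27 CPM for all tested windows. In quiet windows the nrde-3 set-25 libraries, at 0.0164, 0.00837 and 0.00798 CPM, were also above nrde-3, though less so than nrde-3 met-2. The 10207 were 4424, 6311 and 5809 without N2 replicate c or lin-61 replicates a or c. The windows higher in nrde-3 set-25 were 2392, and 989, 1423 and 481 without nrde-3 replicates a, b and c and 663 and 1454 without nrde-3 set-25 replicates a and c. Those higher in nrde-3 met-2 were 6492, and 11836, 12183 and 10784 without nrde-3 replicates a, b and c and 18226 without nrde-3 met-2 replicate b, and 2043 with background subtracted.

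The libraries labelled lin-61 met-2 may carry a wrong label and hold the genotype of nrde-3 set-25. In stretches that were found in these same libraries, they were at 0.12 of N2 on X, where every nrde-3 genotype is low and lin-61 and lin-61 set-25 are at 0.857 and 0.653. On I, where lin-61 and lin-61 set-25 are low, they were at 1.07 of N2. Both stretches were selected by such levels, so these ratios are no separate test of a lin-61 strain that reached the same expression state. In the search over all splits, 0 windows were low in exactly the genotypes labelled lin-61. Over all windows edgeR and DESeq2 called 0 between the libraries labelled lin-61 met-2 and nrde-3 set-25, with 2432 at an unadjusted p below 0.05 by edgeR. Their mean correlation of log2 CPM was 0.986 with nrde-3 set-25, 0.984 among themselves and 0.961 with lin-61 set-25. The same libraries counted under both labels are argued against by the lowest chi-square per degree of freedom between any pair, 4.26, where a resampled copy would give about 1, though this value and the next, 6.2, both between these libraries and nrde-3 set-25, lie below that of every pair within a genotype (lowest 6.44). It stays open which genotype they hold, since replicates b and c, unlike a, have reads in windows that are high in nrde-3 met-2, and since III 13288001 to 13289000 is lost in all 4 double mutants, whichever methyltransferase their label names.

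The windows that differ between nrde-3 and N2, lower or higher, may reflect the library prefix rather than nrde-3. Of the 8027 lower windows, 97.7% had a lower estimate in lin-61 set-25 than in lin-61, against 44.1% of all windows. That pair crosses the same prefixes and shares no library with nrde-3 and N2. Called lower in both were 6464, where independent calls would give 1069. Of the 3838 higher windows, 94.3% had a higher estimate there, against 55.8% of all windows. Called higher in both were 1960 (515.8 for independent calls). With the prefix as a term in the additive model, 163 windows were lower and 1880 higher with the nrde-3 term, and 6813 were lower and 3700 higher with the prefix term. Loss of nrde-3 stays open for part of these windows, because the additive model assumes that mutations do not interact and takes the labels as they stand, including those of lin-61 met-2. The 3838 higher windows were 2080, 1871 and 1152 without N2 replicates a, b and c and 2361 and 1664 without nrde-3 replicates a and b.

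With 3 libraries against 3 there are 10 groupings, too few for a share below 0.05. In each of the 14 comparisons, fitted on its 6 libraries alone, 1 of the 10 groupings, the real one, called as many windows. The real counts were 22380 for lin-61 against N2, 12122 for nrde-3 against N2, 2775 for nrde-3 met-2 against nrde-3, 3820 for nrde-3 set-25 against nrde-3, 25582 for lin-61 met-2 against lin-61, 23713 for lin-61 set-25 against lin-61, 1 for nrde-3 met-2 against lin-61 met-2, 3560 for nrde-3 met-2 against nrde-3 set-25, and 34837, 33497, 29291 and 37689 for nrde-3 met-2, nrde-3 set-25, lin-61 met-2 and lin-61 set-25 against N2. The highest other grouping called 0 in these 12. It called 5 against 162 for nrde-3 set-25 against lin-61 set-25, and 62 against 515 for lin-61 met-2 against lin-61 set-25.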
